A study of Mus musculus with 25 samples.

How the data were processed

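The scanner files hold Cy3 intensity values that, per the file headers, were extracted by Agilent Feature Extraction, background-subtracted and spatially detrended, and not scaled between arrays. The version of Feature Extraction is 10.7.3.1 in the file headers and 9.1 in the submitters' processing notes, and which is right was not given in the sources used here. The headers name the mm9 build for the probe design. Per the labels' protocols, RNA was purified on columns and 0.5 ug was labelled. The deposited series matrix holds the same intensity values times 1 factor per array, on a linear scale, and the rule for the factor was not given in the sources used here.

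The log2 of the processed signal minus the 75th percentile of its array was used here. Each array held 59305 spots other than controls, for 55681 probes, and 26582 probes received a gene symbol through a table of RefSeq names. The other 29099 probes entered no gene result. Probes well above background on at least 5 of the 25 arrays were kept (33504, of which 19625 with a symbol), and a gene took its brightest probe, which gave 15104 genes. A model with 1 mean per group was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3, with p adjusted by Benjamini and Hochberg over the genes of a comparison. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

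The groups and main comparisons were fixed before the data were examined. The replicate numbers did not pair mice, as 4 of 25 arrays matched best with their own number and the median correlation of same-number pairs was -0.013. No 2 arrays were identical. The genes named were the 10 higher and 10 lower genes with the largest change among those that passed and whose arrays did not overlap, or 5 and 5 for the interaction and for 24 against 3 hr. For the interaction, non-overlap compared BW245C arrays minus the vehicle mean at 24 hr with those at 3 hr. Some list members among the 4 with the smallest p were added, and Ptgdr, Ptgdr2, Ptgds, Hpgds, Ifng, Tnf, Il6, Il10 and Il4 were always named. A few genes that these rules chose are not reported here.

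The 41 gene lists, with 803 members of which 750 were measured, were written from general knowledge of liver biology, and those with at least 4 measured members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation, fry and an exact permutation test of per-mouse list means were run beside it. Mouse scores were tested by exact permutation over 252 splits.

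In 15104 simulated genes the steps found 28, 47, 50 and 50 of 50 genes changed 1.5-, 2-, 4- and 8-fold. They called 16 of 14879 unchanged genes, a shifted list and 0 of 40 unshifted lists. Other splits of the real arrays called up to 32 lists.

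Alternatives were normexp background with an offset of 50 (on the median signal, as the planned mean signal was not used here), quantile normalization, a median over probes found on all arrays, no filter, a filter on all 25 arrays, the slide as a fixed or random block, a replicate block, and only the groups compared. The others were an intensity trend, array weights, the mean of probes, the series matrix values, leaving out each mouse, a 2-fold minimum, a threshold of 0.01, other score genes or a median score, split vehicle arrays and other list tests. Added after the files were seen were all features named or not, the arrays of 1 slide, the permutation test of list means, and the overlap of calls with split vehicle arrays.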

Results

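Liver RNA from 25 female C57BL/6 mice was measured on 25 single-colour Agilent arrays, 1 array per mouse, in 5 groups of 5 mice. Untreated mice formed the control group. The other mice received 10 mg/kg concanavalin A (ConA), a plant lectin that activates T cells and inflames the liver, and 15 minutes later either vehicle or 1 mg/kg BW245C. BW245C is an agonist of DP1, a receptor for prostaglandin D2. Livers were collected at 3 or 24 hr. The share of spots well above background ranged from 52.2% to 61.6% of the spots of an array, no spot was saturated, and the number of arrays limits the precision of every value. Each comparison set 5 mice against 5, values after ± are standard errors from the limma fit, and a change was called at an adjusted p under 0.05 over 15104 genes.

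The arrays lay on 5 slides that were entangled with the groups. Slide 1 held 4 untreated arrays and 1 of ConA + vehicle at 3 hr, and slide 2 held 1 untreated array, 2 of ConA + vehicle at 3 hr and 1 of ConA + BW245C at 24 hr. Slide 3 held all 5 arrays of ConA + BW245C at 3 hr, 2 of ConA + vehicle at 3 hr and 1 of ConA + vehicle at 24 hr. Slide 4 held 4 arrays of ConA + vehicle and 3 of ConA + BW245C at 24 hr, and slide 5 held the remaining array of ConA + BW245C at 24 hr. Values with the slide as a block, and within a slide where it held both groups, are therefore given beside the results. No slide held both untreated and ConA + vehicle 24 hr arrays.

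The gene of the targeted receptor, Ptgdr, was not well above background on any of the 25 arrays, and neither was Ptgdr2, which encodes the other prostaglandin D2 receptor. Hpgds, the haematopoietic prostaglandin D synthase, was well above background on 2 untreated arrays and on no array of a ConA group. These 3 genes were not tested. Ptgds, the other prostaglandin D synthase, was measured on all arrays and had a log2 change of -0.32 ± 0.44 at 3 hr after ConA, which did not pass (adjusted p = 0.537). At 24 hr after ConA it was 3.17-fold (log2 -1.67 ± 0.44, adjusted p = 0.00204) lower, although not with the slide as a block (adjusted p = 0.375).

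**Figure D1:**
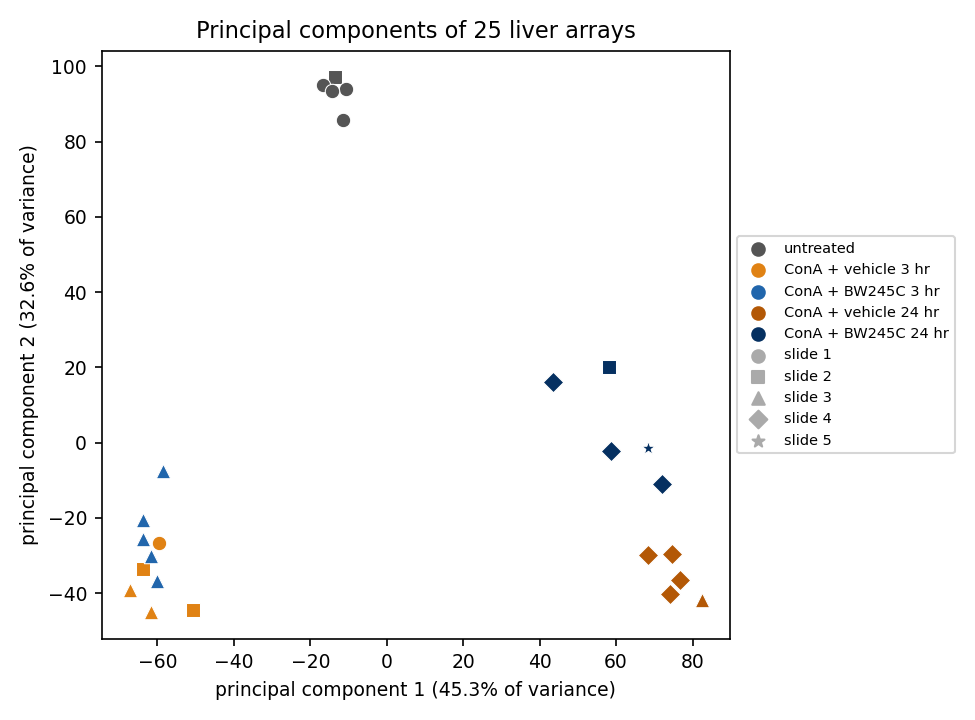
Principal components 1 (45.3% of the variance) and 2 (32.6%) of the 25 arrays, from log2 signals of 15104 genes in arbitrary units, with each point an array, coloured by group and shaped by slide. Untreated, 3 hr and 24 hr arrays form separate clusters, and at 24 hr the 5 BW245C arrays all lie above the 5 vehicle arrays on component 2.

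The comparison of ConA + vehicle with untreated livers at 3 hr asked what the lectin, given with vehicle, changed early. Chemokine genes made up most of the largest increases. Cxcl10, an interferon-induced attractant of T cells, rose 472-fold (log2 8.88 ± 0.28, adjusted p = 1.57e-17), and 533-fold with the slide as a block, 475-fold within slide 1 and 618-fold within slide 2. Ccl7, an attractant of monocytes, rose 522-fold (adjusted p = 3.96e-16), and the neutrophil attractant Cxcl1 rose 363-fold (adjusted p = 4.33e-18). Another 3 chemokine genes were not well above background on any untreated array. For such genes a bound is given as at least N-fold, the brighter group's mean over the dimmer group's mean after each dim array's value was raised to the lowest signal of a probe well above background on it. Cxcl2 rose at least 220.4-fold (adjusted p = 1.96e-14), Ccl11 at least 125-fold (adjusted p = 5.61e-18) and Ccl1 at least 82.3-fold (adjusted p = 1.04e-12). Also among the largest increases were Olr1, a receptor for oxidised lipoprotein, at least 183-fold (adjusted p = 6.35e-14), Ch25h, a cholesterol hydroxylase of the antiviral response, at least 175-fold (adjusted p = 1.1e-13), and Saa3, an acute phase protein, 320.2-fold (adjusted p = 1.99e-18). Ccl7 was above background on 2 untreated arrays.

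G6pc, the glucose 6-phosphatase of gluconeogenesis, was 337-fold (log2 -8.40 ± 0.48, adjusted p = 6.54e-13) lower at 3 hr after ConA, and 325-fold with the slide as a block, 242-fold within slide 1 and 497-fold within slide 2. Cyp7a1, which catalyses the rate-limiting step of bile acid synthesis, was 138-fold (log2 -7.11 ± 0.71, adjusted p = 8.2e-09) lower, and G0s2, an inhibitor of fat breakdown, 74.7-fold (adjusted p = 1.2e-14) lower. Lower by bounds were Sox18, an endothelial transcription factor, at least 15.6-fold (adjusted p = 3.47e-16), the lipase gene Pnpla5, at least 12.9-fold (adjusted p = 1.76e-10), and Cbx2, a Polycomb subunit, at least 12.8-fold (adjusted p = 6.35e-14). Ccnf, a cyclin, was 56.6-fold (adjusted p = 1.44e-12) lower, Chrna4, an acetylcholine receptor subunit, 54.1-fold (adjusted p = 3.39e-06), Pth1r, the parathyroid hormone receptor, 30.5-fold (adjusted p = 4.42e-15), and Spata2l, whose function is little known, 28.9-fold (adjusted p = 1.35e-11). Cyp7a1, Ccnf and Chrna4 were above background on 3, 3 and 2 vehicle arrays. Without ConA + vehicle 3 hr replicate 5 Cyp7a1 stood at -7.73 on the log2 scale. The 20 genes of largest change kept their direction with the slide as a block.

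In all, 3769 genes rose and 5594 fell at 3 hr after ConA, 3430 of them by at least 2-fold. With the slide as a block 8131 were called, of which 7668 were the same genes in the same direction. In 47.4% of the genes tested the arrays of the groups did not overlap, against 0.794% by chance. The authors' series matrix values moved the median of all genes by -0.11 on the log2 scale in this comparison.

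Inflammatory programmes rose at 3 hr after ConA. Parentheses after a list give the members called when adjusted over the list alone, the mean log2 change and its adjusted p, also with an estimated correlation. Every called list kept its direction with the slide as a block and within slides 1 and 2, its mean moving by at most 0.142, 0.428 and 0.501, and all 20 were called with the block. Among interferon response genes 28 of 29 measured rose (28 over the list alone, mean 4.06, adjusted p = 1.65e-22, p = 0.0813 with an estimated correlation), among them Cxcl9, a T cell attractant, 181-fold. All 27 acute phase genes rose (27 over the list alone, mean 2.70, adjusted p = 1.04e-17, p = 0.0813 with an estimated correlation). All 17 NF-kappaB targets rose (17 over the list alone, mean 3.57, adjusted p = 5.45e-16, p = 0.0813 with an estimated correlation). Of 22 chemokine genes 19 rose and 2 fell (21 over the list alone, mean 4.25, adjusted p = 8.24e-11, p = 0.118 with an estimated correlation). The mean was 2.69 with normexp, which draws dim signals together, and 2.62 with a strict filter on all 25 arrays.

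T cell and inflammatory cytokines rose in 21 of 26 genes at 3 hr after ConA (21 over the list alone, mean 2.57, adjusted p = 1.26e-10, p = 0.0813 with an estimated correlation). Their mean was 1.25 with normexp and 1.21 with the strict filter. Ifng, the main cytokine of type 1 T cells and NK cells, rose 101-fold (log2 6.66 ± 0.25, adjusted p = 3.34e-16), Il6, the inducer of the acute phase, 55.3-fold (log2 5.79 ± 0.34, adjusted p = 1.04e-12), and the type 2 cytokine gene Il4 8.66-fold (adjusted p = 5.24e-14). Tnf rose at least 38.3-fold (adjusted p = 1.4e-12). Above background were 3 untreated arrays for Ifng, 1 for Il6, 4 for Il4 and none for Tnf. Il10, an anti-inflammatory cytokine, was above background on 1 vehicle array and no untreated array, so no fold is given. JAK-STAT feedback genes rose in 15 and fell in 2 of 19 (18 over the list alone, mean 2.90, adjusted p = 1.14e-07, p = 0.00986 with an estimated correlation). That call held with an estimated correlation, as did the call of the same list for ConA + BW245C against untreated livers at 3 hr (adjusted p = 0.0139). Immediate early genes rose in 18 and fell in 2 of 25 (21 over the list alone, mean 2.12, adjusted p = 1.06e-07, p = 0.147 with an estimated correlation).

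Among markers of blood cells, neutrophil genes rose in 13 and fell in 1 of 19 at 3 hr after ConA (14 over the list alone, mean 3.08, adjusted p = 2.6e-07, p = 0.173 with an estimated correlation). T and NK lymphocyte markers rose in 18 and fell in 1 of 23 (19 over the list alone, mean 0.93, adjusted p = 3.06e-05, p = 0.261 with an estimated correlation). With normexp the neutrophil and lymphocyte means were 1.71 and 0.60. Platelet markers rose in 6 and fell in 2 of 8 (8 over the list alone, mean 1.39, adjusted p = 0.00919, p = 0.173 with an estimated correlation), but the mean was 0.60 with normexp, and 0.29 and not called (adjusted p = 0.337) with the strict filter. Erythroid markers rose in 5 of 7 (6 over the list alone, mean 1.59, adjusted p = 0.0187, p = 0.257 with an estimated correlation). Dendritic cell markers rose in 6 and fell in 1 of 9 (7 over the list alone, mean 0.90, adjusted p = 0.0417, p = 0.379 with an estimated correlation). The dendritic call was lost with the filter (0.0587), with the mean of probes (0.145), and without untreated replicate 2 (0.0534) or ConA + vehicle 3 hr replicate 3 (0.0524), 4 (0.0519) or 5 (0.0522).

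Some stress and vascular lists rose too at 3 hr after ConA, but not endoplasmic reticulum stress (adjusted p = 0.128), heat shock (0.243) or oxidative stress (0.524). p53 and apoptosis genes rose in 15 and fell in 4 of 23 (19 over the list alone, mean 1.28, adjusted p = 4.52e-05, p = 0.308 with an estimated correlation). Genes of endothelial activation rose in 11 and fell in 6 of 22 (17 over the list alone, mean 2.28, adjusted p = 0.000883, p = 0.517 with an estimated correlation). Matrix remodelling genes rose in 10 and fell in 4 of 22 (14 over the list alone, mean 1.26, adjusted p = 0.0107, p = 0.581 with an estimated correlation), with a mean of 0.80 with normexp and with the strict filter. Hypoxia and glycolysis genes rose in 13 and fell in 5 of 23 (18 over the list alone, mean 1.07, adjusted p = 0.0187, p = 0.723 with an estimated correlation).

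Lipid synthesis and sinusoidal genes fell at 3 hr after ConA. Cholesterol synthesis genes fell in 19 of 20 (19 over the list alone, mean -1.24, adjusted p = 0.000211, p = 0.577 with an estimated correlation). Lipogenesis genes fell in 13 of 14 (13 over the list alone, mean -1.73, adjusted p = 0.00064, p = 0.532 with an estimated correlation). Sinusoidal endothelial markers fell in 16 and rose in 1 of 23 (17 over the list alone, mean -1.13, adjusted p = 0.000641, p = 0.532 with an estimated correlation). Hepatocyte secreted proteins rose in 10 of 26 (8 over the list alone, mean 0.16, adjusted p = 0.047, p = 0.845 with an estimated correlation), a small shift that turned to -0.046 with quantile normalization and was 0.25 with the slide as a block. It was not called with normexp (mean 0.10), the series matrix values (0.054), no filter, an intensity trend or fry. In the exact two-sided permutation test of the per-mouse means this list did not pass (adjusted p = 0.178), unlike the other 19 called lists. Its call was also lost without any of 7 arrays, with adjusted p of 0.0793 and 0.0643 without untreated replicates 3 and 4, 0.0704, 0.15 and 0.0532 without ConA + vehicle 3 hr replicates 1, 2 and 3, 0.0522 without ConA + BW245C 3 hr replicate 5 and 0.0521 without ConA + BW245C 24 hr replicate 5.

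The comparison of ConA + vehicle with untreated livers at 24 hr asked what persisted or came later. Ubd, a ubiquitin-like protein induced by interferon, rose 557-fold (adjusted p = 5.44e-16), and 628-fold with the slide as a block. The neutrophil proteins S100a8 and S100a9 rose 234-fold (adjusted p = 1.77e-14) and 210.0-fold (adjusted p = 7.89e-15). Saa3 rose 283-fold (adjusted p = 2.5e-18) and Ccl7 267-fold (adjusted p = 6.62e-15). By bounds, Ch25h rose at least 217-fold (adjusted p = 8.67e-14), the myeloid gene Slfn4 at least 137-fold (adjusted p = 2.92e-14), the decoy receptor gene Il1r2 at least 66.4-fold (adjusted p = 4.33e-13) and the protease inhibitor A2m at least 45.6-fold (adjusted p = 1.34e-12). Ubd and Ccl7 were above background on 4 and 2 untreated arrays.

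Cyp7a1 was 262-fold (log2 -8.03 ± 0.71, adjusted p = 8.38e-10) lower at 24 hr after ConA, and 713-fold with the slide as a block. Cyp8b1, the next hydroxylase of bile acid synthesis, was 65.3-fold (adjusted p = 3.59e-13) lower. Other hepatocyte enzymes among the largest decreases were the methyltransferase Inmt, 119.7-fold (adjusted p = 1.32e-14), the peroxisomal oxidase Hao2, 99.7-fold (adjusted p = 3.56e-10), the carbonic anhydrase Car3, 63.8-fold (adjusted p = 3.99e-12), and the fatty acid synthase Fasn, 63.1-fold (adjusted p = 4.59e-12). Hao2 was above background on 1 vehicle array, replicate 4, without which it fell at least 77.1-fold, and Cyp7a1, above background on 3, stood at -7.45 on the log2 scale without that array. Clec4g, a lectin of sinusoidal endothelium, fell 55.8-fold (adjusted p = 1.04e-14). By bounds, the steroid dehydrogenase gene Hsd3b5 fell at least 45.9-fold (adjusted p = 7.38e-08), the glucose transporter gene Slc2a4 at least 44.7-fold (adjusted p = 5.23e-09) and Pnpla5 at least 16.8-fold (adjusted p = 1.8e-11). Tnf stayed at least 12.6-fold (adjusted p = 1.8e-10) higher, Ifng 22.1-fold (adjusted p = 3.68e-13), Il6 38.2-fold (adjusted p = 4.62e-12), Il4 3.104-fold (adjusted p = 2.47e-09) and Il10 at least 2.12-fold (adjusted p = 1.77e-07), with Ifng, Il6 and Il4 above background on 3, 1 and 4 untreated arrays.

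In all, 4490 genes rose and 5909 fell at 24 hr after ConA (43.2% of the changed genes higher), 4337 of them by at least 2-fold. The authors' series matrix values moved the median of all genes by 0.35 on the log2 scale and turned the split to 7249 higher and 3782 lower (65.7% higher). With the slide as a block 7696 genes were called, 6740 of them the same genes in the same direction and 34 in the opposite direction.

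Hepatocyte functions fell together at 24 hr after ConA, where the means of called lists kept their direction and moved by at most 0.548 with the slide as a block, where 27 of 28 were called. All 26 urea cycle and amino acid genes fell (26 over the list alone, mean -2.30, adjusted p = 6.14e-12, p = 0.156 with an estimated correlation). Cytochrome P450 and conjugation genes fell in 25 and rose in 1 of 28 (26 over the list alone, mean -2.45, adjusted p = 4.86e-10, p = 0.158 with an estimated correlation). All 22 bile acid genes fell (22 over the list alone, mean -2.58, adjusted p = 1.13e-08, p = 0.156 with an estimated correlation). All 14 lipogenesis genes fell (14 over the list alone, mean -3.73, adjusted p = 3.45e-08, p = 0.164 with an estimated correlation). Hepatocyte secreted proteins fell in 25 of 26 (25 over the list alone, mean -0.92, adjusted p = 1.1e-06, p = 0.376 with an estimated correlation). Their mean was -0.48 with quantile normalization and -0.57 with the series matrix values.

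Genes of both liver zones fell at 24 hr after ConA, pericentral ones in 15 of 17 with 1 higher (16 over the list alone, mean -2.06, adjusted p = 8.32e-06, p = 0.156 with an estimated correlation) and periportal ones in 16 of 18 with 1 higher (17 over the list alone, mean -1.43, adjusted p = 0.000118, p = 0.166 with an estimated correlation). Gluconeogenesis and glycogen genes fell in 13 of 16 (14 over the list alone, mean -1.56, adjusted p = 0.000186, p = 0.166 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 20 (18 over the list alone, mean -1.21, adjusted p = 0.000616, p = 0.47 with an estimated correlation). Fatty acid oxidation genes fell in 18 and rose in 1 of 25 (19 over the list alone, mean -0.89, adjusted p = 0.00768, p = 0.53 with an estimated correlation), but lost their call with quantile normalization (mean -0.58) and had a mean of -0.55 with the series matrix values. Sinusoidal endothelial markers fell in 18 and rose in 3 of 23 (22 over the list alone, mean -1.45, adjusted p = 0.000828, p = 0.395 with an estimated correlation). Kupffer cell markers fell in 10 of 14 (11 over the list alone, mean -1.49, adjusted p = 0.0213, p = 0.486 with an estimated correlation). The Kupffer call was lost with the slide as a block (mean -0.95, adjusted p = 0.172) and with the strict filter (0.0612).

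Inflammatory genes stayed high at 24 hr after ConA. All 29 interferon response genes were higher (29 over the list alone, mean 3.55, adjusted p = 7.98e-19, p = 0.156 with an estimated correlation). Acute phase genes rose in 23 of 27 (24 over the list alone, mean 2.37, adjusted p = 1.42e-10, p = 0.156 with an estimated correlation). Chemokines rose in 18 and fell in 2 of 22 (21 over the list alone, mean 3.29, adjusted p = 8.11e-08, p = 0.156 with an estimated correlation). Cytokines rose in 21 and fell in 2 of 26 (23 over the list alone, mean 2.08, adjusted p = 9.46e-08, p = 0.156 with an estimated correlation). The means were 1.91 and 0.77 with normexp, and 2.15 and 1.09 with the strict filter. NF-kappaB targets rose in 16 of 17 (16 over the list alone, mean 1.75, adjusted p = 2.94e-07, p = 0.164 with an estimated correlation). Immediate early genes rose in 18 and fell in 3 of 25 (21 over the list alone, mean 1.67, adjusted p = 1.68e-05, p = 0.166 with an estimated correlation), with a mean of 1.09 with normexp and 1.04 with the filter. JAK-STAT feedback genes rose in 12 and fell in 2 of 19 (14 over the list alone, mean 1.84, adjusted p = 0.000437, p = 0.156 with an estimated correlation).

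Of the blood cell lists 2 rose at 24 hr after ConA, and the B cell, monocyte, dendritic, platelet and erythroid lists were not called. T and NK lymphocyte markers rose in 21 and fell in 1 of 23 (22 over the list alone, mean 2.24, adjusted p = 3.18e-10, p = 0.156 with an estimated correlation). Neutrophil markers rose in 15 of 19 (15 over the list alone, mean 4.02, adjusted p = 2.76e-08, p = 0.156 with an estimated correlation). Their mean was 2.65 with the strict filter. Cell cycle genes rose in 24 and fell in 1 of 28 (26 over the list alone, mean 1.92, adjusted p = 9.84e-10, p = 0.156 with an estimated correlation). With normexp the lymphocyte, neutrophil and cell cycle means were 1.41, 2.34 and 1.01. MHC class II genes rose in 5 of 12 (5 over the list alone, mean 0.72, adjusted p = 0.0266, p = 0.491 with an estimated correlation), a call lost without ConA + vehicle 24 hr replicate 2 (adjusted p = 0.0584), with quantile normalization (0.05) and with the series matrix values (0.0854).

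Some stress lists rose as well at 24 hr after ConA, but not heat shock (adjusted p = 0.199) or oxidative stress (0.22). p53 and apoptosis genes rose in 19 and fell in 2 of 23 (21 over the list alone, mean 1.54, adjusted p = 3.35e-07, p = 0.156 with an estimated correlation). Matrix remodelling genes rose in 17 and fell in 3 of 22 (21 over the list alone, mean 1.90, adjusted p = 1.35e-05, p = 0.176 with an estimated correlation), with a mean of 1.08 with normexp and 1.26 with the strict filter. Genes of endothelial activation rose in 17 and fell in 3 of 22 (20 over the list alone, mean 2.04, adjusted p = 4.02e-05, p = 0.238 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 and fell in 3 of 23 (19 over the list alone, mean 1.56, adjusted p = 7.1e-05, p = 0.31 with an estimated correlation). Endoplasmic reticulum stress genes rose in 17 and fell in 1 of 22 (18 over the list alone, mean 1.20, adjusted p = 7.4e-05, p = 0.166 with an estimated correlation).

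The comparison of ConA + BW245C with ConA + vehicle at 3 hr asked what the DP1 agonist changed early. The largest change was a fall of Ddit4, a stress-induced inhibitor of mTOR signalling, which was 19.5-fold (log2 -4.28 ± 0.39, adjusted p = 2.26e-07) lower, and 15.8-fold lower within slide 3. Dusp1, a phosphatase that limits MAP kinase signalling, was 8.56-fold (adjusted p = 4.5e-07) lower (10.5-fold within slide 3), and Ptgs2, the inducible cyclooxygenase, 8.12-fold (log2 -3.02 ± 0.52, adjusted p = 0.000225) lower (9.09-fold within slide 3). Also lower were Nos2, the inducible nitric oxide synthase, 10.1-fold (adjusted p = 2.63e-07), Gdf15, a stress-induced cytokine, 12.04-fold (adjusted p = 1.23e-06), the ephrin gene Efna1, 8.57-fold (adjusted p = 2.52e-05), and the interferon-induced gene Ifit2, 7.65-fold (adjusted p = 1.08e-05). By bounds, Ankrd1, a mechanical stress gene, was at least 4.14-fold (adjusted p = 2.52e-06) lower, Duoxa2, a maturation factor of an oxidase, at least 3.31-fold (adjusted p = 3.37e-08), and the clock gene Ciart at least 1.79-fold (adjusted p = 4e-04). Above background were 3 BW245C arrays for Ptgs2 and 4 vehicle arrays for Ciart.

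Ppp1r3g, which directs a phosphatase to glycogen, had the largest increase with BW245C at 3 hr, 8.18-fold (log2 3.03 ± 0.52, adjusted p = 0.000231) (8.23-fold within slide 3), and G6pc, which ConA had lowered, rose 6.25-fold (log2 2.64 ± 0.48, adjusted p = 0.000401) (5.703-fold within slide 3, and log2 2.00 without ConA + BW245C 3 hr replicate 5). Pdk4, which restrains glucose oxidation, rose 4.45-fold (adjusted p = 4.27e-05) and the mitochondrial carrier gene Slc25a34 5.41-fold (adjusted p = 9.18e-06). Arntl, a core activator of the circadian clock, rose 3.45-fold (adjusted p = 2.5e-05). The others were the calcium-binding protein gene S100g, 5.74-fold (adjusted p = 0.000178), the ubiquitin ligase genes Rnf144a, 4.16-fold (adjusted p = 2.69e-05), and Spsb4, 3.47-fold (adjusted p = 0.000296), the centriole gene Fbf1, 3.32-fold (adjusted p = 0.000111), and the protease gene Adamts15, at least 1.96-fold (adjusted p = 4.81e-05), which was above background on 4 BW245C arrays and no vehicle array and was not called with normexp (adjusted p = 0.126). Vehicle arrays above background numbered 3 for Ppp1r3g, 4 for Slc25a34 and 2 for S100g. These 20 genes were all called with the slide as a block.

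Of the cytokines of ConA hepatitis, Il4 was 2.15-fold (log2 1.11 ± 0.16, adjusted p = 2.74e-05) higher with BW245C at 3 hr (2.04-fold with the slide as a block, 1.87-fold within slide 3). Ifng, Tnf and Il6 had log2 changes of -0.32 ± 0.25, -0.49 ± 0.37 and -0.75 ± 0.34, and did not pass (adjusted p = 0.336, 0.337 and 0.0996). Il6 passed without ConA + vehicle 3 hr replicate 2 (-1.03, adjusted p = 0.0278) and without ConA + BW245C 3 hr replicate 2 (-0.95, 0.0499). Il10, above background on 1 vehicle and 4 BW245C arrays, was higher by an uncertain size (adjusted p = 0.0436), but not with the slide as a block (adjusted p = 0.499), with normexp (0.682) or in several other settings. Without BW245C replicate 2, 4 or 5 its adjusted p was 0.0717, 0.127 or 0.0929, and without vehicle replicate 2 or 3 it was 0.117 or 0.126. Ptgds did not pass (adjusted p = 0.488).

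In all, 1773 genes rose and 2544 fell with BW245C at 3 hr (41.1% higher), 572 of them by at least 2-fold. The series matrix values moved the median of all genes by 0.12 and gave 2870 higher and 1752 lower (62.1% higher). With the slide as a block 1770 genes were called, 1441 of them the same genes in the same direction. Within slide 3, with 5 BW245C and 2 vehicle arrays, 330 were called. The groups' arrays did not overlap in 13.5% of genes, against 0.794% by chance.

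Several inflammatory lists fell with BW245C at 3 hr, but the cytokine (mean -0.163, adjusted p = 0.728), neutrophil (-0.053, 0.832) and JAK-STAT feedback lists (-0.416, 0.184, though 0.0318 with the slide as a block) were not called. None of the 9 list calls held with an estimated correlation, and 71 of 100 array splits called as many. The means of called lists kept their direction, moving by at most 0.235 with the slide as a block, where all but the heat shock list (adjusted p = 0.0668) were called, and 0.285 within slide 3. Interferon response genes fell in 22 of 29 (23 over the list alone, mean -0.94, adjusted p = 1.14e-10, p = 0.949 with an estimated correlation). Acute phase genes fell in 16 of 27 (20 over the list alone, mean -0.52, adjusted p = 9.91e-06, p = 0.949 with an estimated correlation). Their mean was -0.29 with the slide as a block. NF-kappaB targets fell in 13 of 17 (15 over the list alone, mean -0.60, adjusted p = 2e-05, p = 0.949 with an estimated correlation). Chemokines fell in 12 and rose in 1 of 22 (14 over the list alone, mean -0.72, adjusted p = 0.00224, p = 0.949 with an estimated correlation). That call was lost with the strict filter (mean -0.44, adjusted p = 0.22). Immediate early genes fell in 13 of 25 (13 over the list alone, mean -0.83, adjusted p = 0.000261, p = 0.949 with an estimated correlation).

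Of the stress lists 2 fell with BW245C at 3 hr, hypoxia and heat shock, while the p53 (mean -0.288, adjusted p = 0.0625), endoplasmic reticulum (-0.372, 0.0625) and oxidative stress lists (0.103, 0.728) were not called. Hypoxia and glycolysis genes fell in 11 and rose in 1 of 23 (14 over the list alone, mean -0.68, adjusted p = 0.00224, p = 0.949 with an estimated correlation). Heat shock genes fell in 7 and rose in 1 of 13 (9 over the list alone, mean -0.48, adjusted p = 0.0101, p = 0.949 with an estimated correlation). Matrix remodelling genes fell in 8 of 22 (8 over the list alone, mean -0.54, adjusted p = 0.0147, p = 0.949 with an estimated correlation). The matrix call was lost without ConA + vehicle 3 hr replicate 1 (mean -0.43, adjusted p = 0.0774) or 4 (-0.52, 0.0599), or with the strict filter (0.0629). Sinusoidal endothelial markers rose in 6 of 23 (6 over the list alone, mean 0.31, adjusted p = 0.00529, p = 0.949 with an estimated correlation). That call was lost with fry (adjusted p = 0.142) and without ConA + vehicle 3 hr replicate 2 (mean 0.21, adjusted p = 0.062). In the exact permutation test of the per-mouse means the sinusoidal list (adjusted p = 0.296) and the matrix list (adjusted p = 0.0501) did not pass, and the other 7 did.

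**Figure D2:**
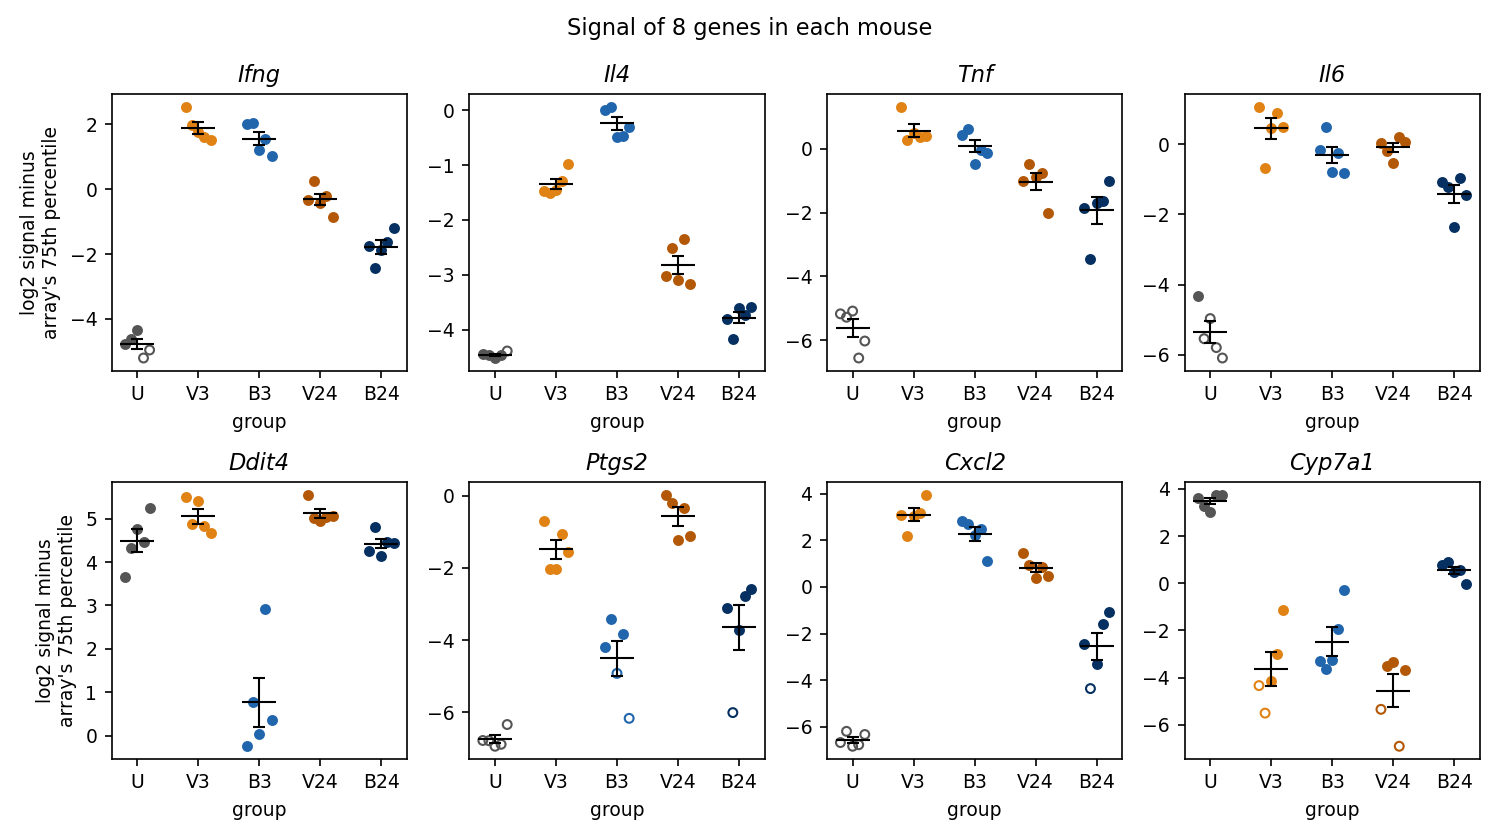
Log2 signal minus the array's 75th percentile (y axis, log2 units) of 8 genes in the 5 groups (x axis: U untreated, V3 and V24 ConA + vehicle, B3 and B24 ConA + BW245C at 3 and 24 hr), a point per mouse, open where not well above background, with bars at mean ± SE (n = 5). Ddit4 at 3 hr and Ptgs2 at both times lie lower with BW245C (19.5-, 8.12- and 8.37-fold), Il4 lies 2.15-fold higher at 3 hr and 1.94-fold lower at 24 hr, and Cyp7a1 lies 34.2-fold higher at 24 hr.

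The comparison of ConA + BW245C with ConA + vehicle at 24 hr asked what the agonist changed late. Cyp7a1 was 34.2-fold (log2 5.10 ± 0.71, adjusted p = 3.12e-05) higher (51.5-fold with the slide as a block, 34.6-fold within slide 4), and Cyp8b1 8.27-fold (adjusted p = 4.08e-06) higher (7.09-fold within slide 4). Steroid dehydrogenases of hepatocytes rose, Hsd3b3 7.43-fold (adjusted p = 8.11e-06), Hsd3b2 6.89-fold (adjusted p = 1.2e-05), Hsd3b6 6.75-fold (adjusted p = 8e-06) and Hsd3b5 at least 8.599-fold (adjusted p = 0.000603). Inmt rose 5.72-fold (adjusted p = 9.53e-06), the acyltransferase gene Keg1 6.58-fold (adjusted p = 1.2e-05) and the lectin gene Clec2h at least 2.92-fold (adjusted p = 9.89e-05). The pancreatic elastase gene Cela2a, at least 9.89-fold (adjusted p = 0.0229) higher by its bound, was far above the rest in ConA + BW245C 24 hr replicate 4, an array with high exocrine pancreas markers, and at least 2.66-fold higher without it. It was not called with normexp (adjusted p = 0.0744) or from only the groups compared (0.13). Cyp7a1, above background on 3 vehicle arrays, had a log2 change of 4.51 without ConA + vehicle 24 hr replicate 4.

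The neutrophil attractants Cxcl3 and Cxcl2 were, with BW245C at 24 hr, 14.3-fold (log2 -3.84 ± 0.49, adjusted p = 1.25e-05) and 10.4-fold (log2 -3.38 ± 0.45, adjusted p = 2.06e-05) lower (15.8-fold and 11.1-fold within slide 4), and Ptgs2 was 8.37-fold (log2 -3.07 ± 0.52, adjusted p = 0.000182) lower (9.46-fold within slide 4, and log2 -2.47 without ConA + BW245C 24 hr replicate 2). Prok2, a chemokine-like neutrophil product, fell 7.62-fold (adjusted p = 4.55e-06), Ankrd1 7.14-fold (adjusted p = 4.92e-05), the myeloid gene Ankrd22 6.08-fold (adjusted p = 0.000179) and the protease inhibitor Cstdc4 5.32-fold (adjusted p = 0.000458). The oestrogen sulfotransferase Sult1e1 fell 6.51-fold (adjusted p = 0.00149) and the bile acid sulfate transporter Slc10a6 5.47-fold (adjusted p = 0.00233). BW245C arrays above background numbered 1 for Prok2, 2 for Cxcl3 and Ankrd22, 3 for Ankrd1 and 4 for Cxcl2, Ptgs2 and Cstdc4. Csf3, the granulocyte growth factor, fell at least 2.099-fold (adjusted p = 0.0415), was above background on 4 vehicle arrays and no BW245C array, and lost its call with the slide as a block (adjusted p = 0.0915), normexp (0.391) and other settings. Its adjusted p also rose to between 0.0536 and 0.0906 without any 1 of the 10 arrays compared except ConA + vehicle 24 hr replicate 3. Of the 20 genes of largest change 19 were called with the slide as a block.

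Most of the named cytokine genes were lower with BW245C at 24 hr. Ifng was 2.77-fold (log2 -1.47 ± 0.25, adjusted p = 0.000166) lower (3.12-fold within slide 4), Il6 2.51-fold (log2 -1.33 ± 0.34, adjusted p = 0.00606) (1.96-fold), Il4 1.94-fold (log2 -0.96 ± 0.16, adjusted p = 0.000116) (2.18-fold) and Il10 2.05-fold (log2 -1.03 ± 0.24, adjusted p = 0.00308) (1.89-fold), the last above background on 5 vehicle and 2 BW245C arrays and not called with normexp (adjusted p = 0.0861). Tnf had a log2 change of -0.91 ± 0.37 and did not pass (adjusted p = 0.0758), though it did without ConA + BW245C 24 hr replicate 5 (-1.14, adjusted p = 0.03) or ConA + vehicle 24 hr replicate 5 (-1.15, 0.0263). Ptgds had a log2 change of -1.18 ± 0.44 and did not pass (adjusted p = 0.0531), but passed without ConA + vehicle 24 hr replicate 2 (-1.42, adjusted p = 0.029). It also passed without some arrays outside the comparison, ConA + vehicle 3 hr replicates 1 (0.045), 4 (0.0472) and 5 (0.0417) and ConA + BW245C 3 hr replicates 2 (0.0308) and 5 (0.041).

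In all, 2656 genes rose and 1351 fell with BW245C at 24 hr (66.3% higher), 641 of them by at least 2-fold. The series matrix values moved the median of all genes by -0.11 and gave 1956 higher and 2614 lower (42.8% higher). With the slide as a block 4326 genes were called, 3257 of them the same genes in the same direction. Within slide 4, with 3 BW245C and 4 vehicle arrays, 369 were called.

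Hepatocyte functions rose with BW245C at 24 hr, and none of the 26 list calls held with an estimated correlation. The means kept their direction, moving by at most 0.186 with the slide as a block, where 22 were called, and 0.225 within slide 4. Not called with the block were the lipogenesis (adjusted p = 0.0915), lymphocyte (0.0672), sinusoidal (0.0677) and cholangiocyte (0.0831) lists. Cytochrome P450 and conjugation genes rose in 26 of 28 (27 over the list alone, mean 1.09, adjusted p = 6.65e-17, p = 0.135 with an estimated correlation). Bile acid genes rose in 17 of 22 (19 over the list alone, mean 1.19, adjusted p = 2.08e-11, p = 0.135 with an estimated correlation). Urea cycle and amino acid genes rose in 17 of 26 (20 over the list alone, mean 0.62, adjusted p = 2.48e-09, p = 0.235 with an estimated correlation). Hepatocyte secreted proteins rose in 17 of 26 (20 over the list alone, mean 0.42, adjusted p = 1.61e-08, p = 0.343 with an estimated correlation). Pericentral genes rose in 13 of 17 (16 over the list alone, mean 0.87, adjusted p = 5.12e-08, p = 0.135 with an estimated correlation). Periportal genes rose in 9 and fell in 1 of 18 (12 over the list alone, mean 0.48, adjusted p = 0.000956, p = 0.293 with an estimated correlation).

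Some other metabolic and resident cell lists rose with BW245C at 24 hr. Cholesterol synthesis genes rose in 7 of 20 (8 over the list alone, mean 0.44, adjusted p = 0.00404, p = 0.61 with an estimated correlation). Gluconeogenesis and glycogen genes rose in 7 and fell in 1 of 16 (9 over the list alone, mean 0.41, adjusted p = 0.007, p = 0.354 with an estimated correlation). Lipogenesis genes rose in 3 of 14 (3 over the list alone, mean 0.43, adjusted p = 0.034, p = 0.642 with an estimated correlation). Stellate cell and fibroblast markers rose in 8 of 17 (10 over the list alone, mean 0.37, adjusted p = 0.0266, p = 0.328 with an estimated correlation). Sinusoidal endothelial markers rose in 8 of 23 (9 over the list alone, mean 0.34, adjusted p = 0.0403, p = 0.663 with an estimated correlation). The array with high exocrine pancreas markers moved none of these lists past the threshold, as each kept its call without it.

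Most inflammatory lists fell with BW245C at 24 hr, but acute phase proteins were not called (mean -0.043, adjusted p = 0.827). NF-kappaB targets fell in 14 of 17 (16 over the list alone, mean -0.74, adjusted p = 2.33e-09, p = 0.141 with an estimated correlation). Neutrophil markers fell in 13 of 19 (13 over the list alone, mean -1.19, adjusted p = 2.32e-08, p = 0.141 with an estimated correlation). Interferon response genes fell in 20 of 29 (20 over the list alone, mean -0.62, adjusted p = 2.32e-08, p = 0.293 with an estimated correlation). Cytokines fell in 17 and rose in 1 of 26 (21 over the list alone, mean -0.87, adjusted p = 2.32e-08, p = 0.141 with an estimated correlation). Their mean was -0.33 with normexp, and -0.36 and not called (adjusted p = 0.111) with the strict filter. Chemokines fell in 10 and rose in 2 of 22 (15 over the list alone, mean -0.98, adjusted p = 3.6e-06, p = 0.248 with an estimated correlation). Their mean was -0.55 with that filter. Immediate early genes fell in 14 of 25 (17 over the list alone, mean -0.70, adjusted p = 7.76e-08, p = 0.141 with an estimated correlation). JAK-STAT feedback genes fell in 7 and rose in 1 of 19 (12 over the list alone, mean -0.51, adjusted p = 0.00155, p = 0.135 with an estimated correlation).

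Most stress and vascular lists fell with BW245C at 24 hr, but not oxidative stress (adjusted p = 0.0648). Hypoxia and glycolysis genes fell in 14 of 23 (14 over the list alone, mean -0.68, adjusted p = 7.69e-08, p = 0.235 with an estimated correlation). Genes of endothelial activation fell in 12 of 22 (13 over the list alone, mean -0.76, adjusted p = 3.33e-05, p = 0.293 with an estimated correlation). p53 and apoptosis genes fell in 7 of 23 (10 over the list alone, mean -0.50, adjusted p = 3.69e-06, p = 0.235 with an estimated correlation). Endoplasmic reticulum stress genes fell in 5 of 22 (5 over the list alone, mean -0.35, adjusted p = 0.00404, p = 0.354 with an estimated correlation). Heat shock genes fell in 2 of 13 (1 over the list alone, mean -0.32, adjusted p = 0.0239, p = 0.6 with an estimated correlation). Matrix remodelling genes fell in 4 and rose in 2 of 22 (10 over the list alone, mean -0.34, adjusted p = 0.034, p = 0.61 with an estimated correlation). T and NK lymphocyte markers fell in 2 of 23 (0 over the list alone, mean -0.17, adjusted p = 0.0378, p = 0.61 with an estimated correlation) and cholangiocyte markers in 1 of 11 (0 over the list alone, mean -0.30, adjusted p = 0.0408, p = 0.235 with an estimated correlation).

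In the exact permutation test of per-mouse means, 20 of the 26 lists passed for BW245C at 24 hr. The cholesterol (adjusted p = 0.145), heat shock (0.113), lipogenesis (0.0592), matrix (0.0678), lymphocyte (0.315) and cholangiocyte (0.0678) lists did not. Other scalings, filters, weights or fry also ended calls of the lipogenesis, sinusoidal, matrix, lymphocyte and cholangiocyte lists, and fry those of the cholesterol (0.061) and heat shock (0.117) lists. Means became -0.11 (matrix, strict filter), -0.23 and -0.14 (matrix and cholangiocyte, normexp), -0.28 (lymphocyte, series matrix) and 0.28 (cholesterol and lipogenesis, array weights). Leaving out 1 array ended the calls of 7 lists, given here with the adjusted p without that array of BW245C (B) or vehicle (V) at 24 hr. The heat shock list lost its call without B replicate 1 (0.0562) or 4 (0.146) or V replicate 4 (0.0541), and the stellate list without V replicate 5 (0.0735). The lipogenesis list lost it without B replicate 2 (0.0576) or 3 (0.0868) or V replicate 1 (0.0706) or 5 (0.0573), and the matrix list without B replicate 2 (0.176) or V replicate 1 (0.0563) or 2 (0.052). The lymphocyte list lost it without B replicate 2 (0.108) or 4 (0.054) or V replicate 1 (0.168) or 2 (0.143). The sinusoidal list lost it without B replicate 1 (0.122) or 5 (0.0696) or V replicate 5 (0.257), and the cholangiocyte list without B replicate 1 (0.104) or 2 (0.0503) or V replicate 2 (0.0538) or 5 (0.0708).

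**Figure D3:**
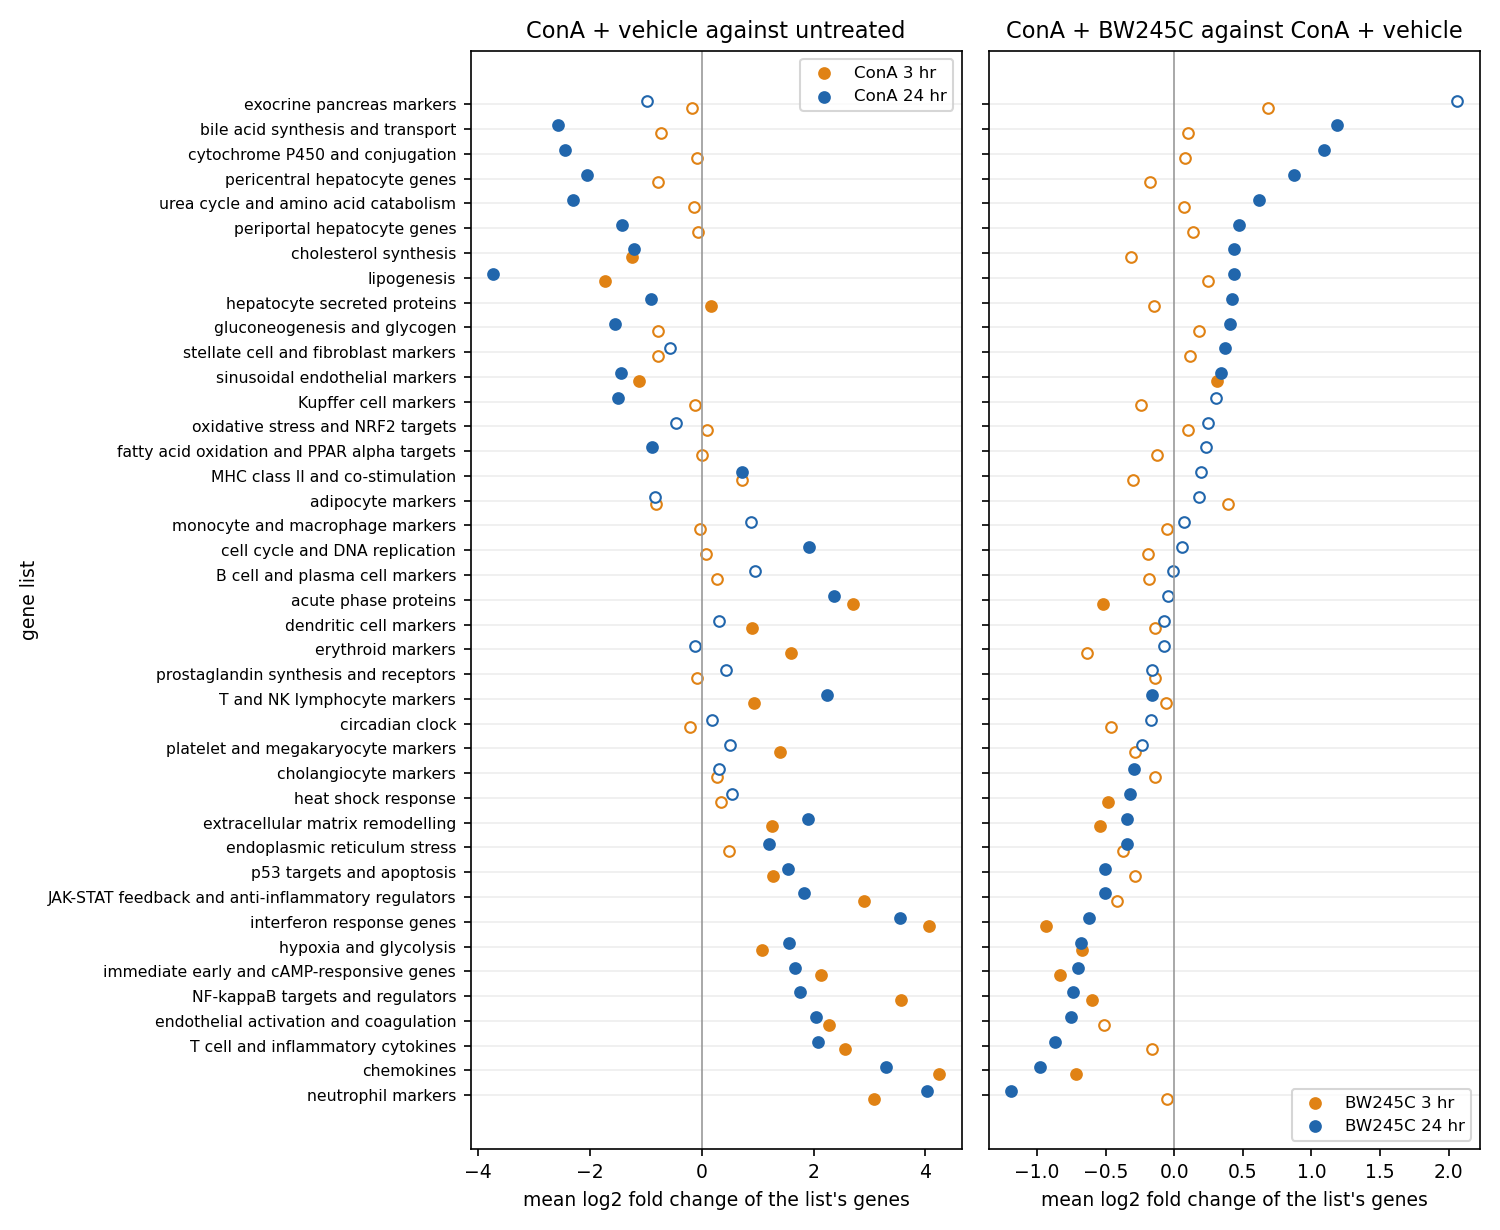
Mean log2 fold change (x axis) of the genes of each list (y axis) for ConA + vehicle against untreated (left) and ConA + BW245C against ConA + vehicle (right) at 3 hr (orange) and 24 hr (blue), n = 5 mice per group, filled where the list was called at an adjusted p under 0.05. At 24 hr the P450 list stands at -2.45 with ConA and at 1.09 with BW245C, and the bile acid list at -2.58 and 1.19.

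The difference between the agonist's effects at 24 and 3 hr was tested as an interaction. Ihh, a hedgehog ligand, had the largest relative rise (adjusted p = 3.35e-06), but no fold is given as it was above background on 4 vehicle and no BW245C arrays at 3 hr. Cyp7a1 (log2 3.95 ± 1.01, adjusted p = 0.00693), Ddit4 (log2 3.59 ± 0.56, adjusted p = 0.000192), Cyp8b1 (log2 3.31 ± 0.47, adjusted p = 8.85e-05) and Hao2 (log2 3.21 ± 0.79, adjusted p = 0.00575) followed. Cyp7a1 was 3.36 without ConA + vehicle 24 hr replicate 4 and 3.33 without ConA + vehicle 3 hr replicate 5. The largest relative falls were in Ppp1r3g (log2 -4.39 ± 0.74, adjusted p = 0.00036), Cxcl3 (log2 -4.23 ± 0.69, adjusted p = 0.000262), Sult1e1 (log2 -4.07 ± 0.82, adjusted p = 0.00145), Pdk4 (log2 -3.85 ± 0.44, adjusted p = 1.09e-05) and Il13, a type 2 cytokine (log2 -3.38 ± 0.54, adjusted p = 0.000238). At 24 hr 1 vehicle array was above background for Hao2 (replicate 4), so its size is uncertain, and 2, 3 and 4 BW245C arrays for Cxcl3, Il13 and Ppp1r3g. Vehicle arrays above background for Cyp7a1 numbered 3 at each time, and for Ppp1r3g 3 at 3 hr. Sult1e1 did not pass with the slide as a block (adjusted p = 0.0595). Il4 differed between the times (log2 -2.06 ± 0.22, adjusted p = 5.53e-06), as did Ifng (log2 -1.14 ± 0.35, adjusted p = 0.0185) and, without the slide as a block, Il10 (adjusted p = 0.00145, 0.0693 with it and 0.12 with normexp). Tnf (adjusted p = 0.57), Il6 (0.378) and Ptgds (0.0555) did not pass. Ptgds did pass without ConA + vehicle 3 hr replicate 3 (0.0472) or 5 (0.0219), ConA + BW245C 3 hr replicate 4 (0.0475) or 5 (0.026), or ConA + vehicle 24 hr replicate 2 (0.0357).

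The interaction was called for 2907 genes in the higher and 1628 in the lower direction (64.1% higher), and for 923 with the slide as a block, 731 of them the same genes in the same direction. The series matrix values moved the median of all genes by -0.23 and gave 1434 higher and 3049 lower (32.0% higher). Among lists, P450 genes were relatively higher at 24 hr in 22 of 28 (23 over the list alone, mean 1.01, adjusted p = 3e-07, p = 0.822 with an estimated correlation), with Cyp2e1 3.51-fold. Likewise higher were hepatocyte secreted proteins in 18 of 26 (23 over the list alone, mean 0.57, adjusted p = 3.07e-07, p = 0.945 with an estimated correlation), and bile acid genes in 13 of 22 (15 over the list alone, mean 1.09, adjusted p = 1.14e-05, p = 0.822 with an estimated correlation), with the uptake transporter Slco1b2 3.22-fold. Pericentral genes were higher in 13 of 17 (16 over the list alone, mean 1.05, adjusted p = 1.29e-05, p = 0.822 with an estimated correlation), with Rgn, a calcium regulator, 5.09-fold. Urea cycle genes were higher in 14 of 26 (17 over the list alone, mean 0.55, adjusted p = 0.000425, p = 0.945 with an estimated correlation). Cholesterol synthesis genes were higher in 9 of 20 (13 over the list alone, mean 0.75, adjusted p = 0.00364, p = 0.945 with an estimated correlation). Acute phase genes were higher in 12 of 27 (16 over the list alone, mean 0.48, adjusted p = 0.00374, p = 0.945 with an estimated correlation), a call lost with the slide as a block (mean 0.12, adjusted p = 0.355), quantile normalization (0.19, 0.398) and normexp (0.067). The other 8 lists were called with the block, but 77 of 100 array splits called 9 or more. The cholesterol call was lost with array weights (0.0807) and fry (0.0726). Neutrophil markers were relatively lower in 11 of 19 (12 over the list alone, mean -1.14, adjusted p = 1.29e-05, p = 0.822 with an estimated correlation), with Retnlg 6.899-fold, and cytokines lower in 9 and higher in 2 of 26 (11 over the list alone, mean -0.71, adjusted p = 0.000825, p = 0.923 with an estimated correlation). The cytokine mean was -0.15 with normexp, and turned to 0.13 with the strict filter (adjusted p = 0.846). Secreted, urea cycle and cholesterol means were 0.29, 0.32 and 0.43 with the slide as a block, and the first 2 were 0.29 and 0.29 with quantile normalization and 0.34 and 0.32 with the series matrix values, where the acute phase mean was 0.25.

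The time course without the agonist compared ConA + vehicle at 24 with 3 hr. The p53 target Phlda3 rose 89.5-fold (log2 6.48 ± 0.20, adjusted p = 1.65e-16) (81.9-fold within slide 3), Ccnf 66.7-fold (adjusted p = 7.92e-13) and G0s2 53.2-fold (adjusted p = 9.02e-14), while Gml, a p53-induced surface protein, rose at least 24.4-fold (adjusted p = 7.57e-12) and Ido1, an interferon-induced tryptophan-degrading enzyme, at least 18.6-fold (adjusted p = 8.82e-10). Ccnf was above background on 3 arrays at 3 hr. Hao2 fell 96.7-fold (adjusted p = 4.12e-10), or at least 74.7-fold without ConA + vehicle 24 hr replicate 4, the 1 array at 24 hr where it was above background. Also lower were Ccl1 81.5-fold (adjusted p = 9.82e-11), Inmt 75.4-fold (adjusted p = 8.75e-14), the corticosteroid-binding globulin gene Serpina6 45.03-fold (adjusted p = 1.12e-13) and Car3 40.9-fold (adjusted p = 2.72e-11). Ccl1 was above background on 3 arrays at 24 hr, and stood at -6.96 without that replicate 4. Ifng fell 4.58-fold (adjusted p = 3.86e-08), Tnf 3.03-fold (adjusted p = 6e-04) and Il4 2.79-fold (adjusted p = 1.22e-08), and Ptgds fell 2.54-fold (adjusted p = 0.0103), though not with the slide as a block (adjusted p = 0.343) or the series matrix values (0.077). Il10, above background on 1 array at 3 hr and 5 at 24 hr, differed (adjusted p = 0.000247), but stood at -0.085 with normexp. Il6 did not pass (adjusted p = 0.173) unless ConA + vehicle 3 hr replicate 2 was left out (0.0321). In all 5011 genes rose and 5327 fell (48.5% higher), 4415 by at least 2-fold and 9671 with the slide as a block, and the series matrix values gave 8343 higher and 2920 lower (74.1% higher). The median of all genes moved by 0.45 with those values, by -0.11 with normexp and by 0.11 with quantile normalization.

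Cell cycle genes rose in 26 and fell in 2 of 28 from 3 to 24 hr with vehicle (28 over the list alone, mean 1.85, adjusted p = 9.26e-08, p = 0.39 with an estimated correlation). T and NK lymphocyte markers rose in 20 and fell in 1 of 23 (21 over the list alone, mean 1.31, adjusted p = 3.26e-05, p = 0.39 with an estimated correlation). Urea cycle genes fell in 25 of 26 (26 over the list alone, mean -2.15, adjusted p = 1.51e-11, p = 0.39 with an estimated correlation). P450 genes fell in 25 and rose in 1 of 28 (26 over the list alone, mean -2.36, adjusted p = 5.44e-10, p = 0.39 with an estimated correlation). NF-kappaB targets fell in 15 and rose in 1 of 17 (16 over the list alone, mean -1.82, adjusted p = 4.76e-06, p = 0.39 with an estimated correlation). Another 10 lists fell, none of them called with an estimated correlation (adjusted p from 0.39 upward), among them all 26 hepatocyte secreted proteins and 6 of 7 erythroid markers. Of these 15 lists 14 were called in the same direction with the slide as a block, but not the Kupffer list (adjusted p = 0.141).

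How far the agonist-treated livers stood from untreated ones was also tested. At 3 hr 4074 genes were higher and 6391 lower than in untreated livers (5177 changed with the slide as a block), and at 24 hr 3440 were higher and 5104 lower (5513 with the block, and 5499 higher and 3178 lower with the series matrix values, which moved the median of all genes by 0.23). Scores of the genes that ConA changed at least 2-fold, chosen from the 10 ConA-treated mice of a time together, compared BW245C and vehicle mouse by mouse. At 24 hr the score of 1794 induced genes was 2.32 ± 0.11 (SD, n = 5) with vehicle and 1.84 ± 0.25 with BW245C, a difference of -0.48 (exact two-sided permutation p = 0.00794, adjusted p = 0.0159, and -0.48 within slide 4, where p = 0.0286 was the smallest possible). The score of 1690 repressed genes was -2.02 ± 0.10 and -1.39 ± 0.21, a difference of 0.63 (exact permutation p = 0.00794, adjusted p = 0.0159, and 0.53 within slide 4, p = 0.0286).

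At 3 hr the score of 1481 induced genes was 2.20 ± 0.10 (SD, n = 5) with vehicle and 1.96 ± 0.21 with BW245C, a difference of -0.24 (exact two-sided permutation p = 0.0476, and -0.30 within slide 3, p = 0.143). The score of 1829 repressed genes was -1.74 ± 0.088 and -1.60 ± 0.095, a difference of 0.14 (exact permutation p = 0.0397, and 0.19 within slide 3, p = 0.0476). These 3 hr calls were lost under several alternatives, and without 1 array the differences ranged from -0.28 to -0.17 and from 0.10 to 0.18.

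**Figure D4:**
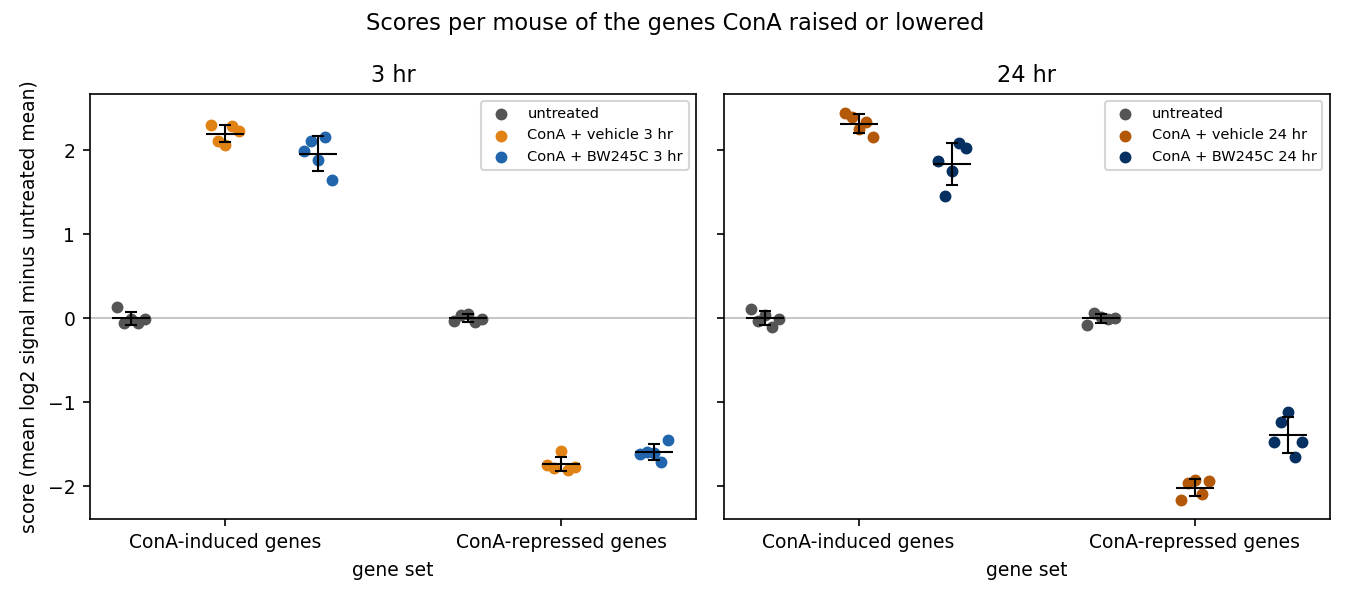
Score per mouse (y axis, mean log2 signal minus the untreated mean) of ConA-induced and ConA-repressed genes (x axis) at 3 hr (left) and 24 hr (right), a point per mouse, with bars at mean ± SD (n = 5). At 24 hr the BW245C mice lie closer to untreated mice than all vehicle mice, at 1.46 to 2.09 against 2.16 to 2.44 for induced genes and at -1.66 to -1.12 against -2.16 to -1.93 for repressed genes.

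Across genes the agonist's effect ran against the lectin's at 24 hr, and less surely at 3 hr. Pearson's r between the effects of BW245C and of ConA was -0.39 at 3 hr and -0.76 at 24 hr over 15104 genes, which are not independent replicates. The vehicle arrays enter both effects with opposite signs and lower r without any agonist effect, so 200 simulations were run with unchanged agonist groups. They gave a mean covariance of -0.027 at 3 hr (lowest -0.14) and -0.021 at 24 hr (lowest -0.27), against -0.21 and -0.45 observed. The lowest simulated r was -0.48 at 3 hr, below the observed value, and -0.64 at 24 hr, above it. With the vehicle arrays split between the effects, r was -0.32 (-0.46 to -0.11 over 20 splits) at 3 hr and -0.71 (-0.75 to -0.63) at 24 hr, and with the slide as a block it was -0.47 and -0.75. At 24 hr 2481 genes fell with ConA and rose with BW245C and 1181 rose and then fell, counts that shared vehicle arrays raise. With no vehicle array in both effects (10 splits), 93.3% of the BW245C calls at 24 hr ran opposite to a ConA call, against 34.1% for independent calls. At 3 hr this was 60.6 to 71.2% against 26.1 to 27.9% in 7 splits, but 33.0 to 34.4% against 30.0 to 30.3%, almost as by chance, in the 3 whose BW245C effect used no vehicle array of slide 3.

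**Figure D5:**
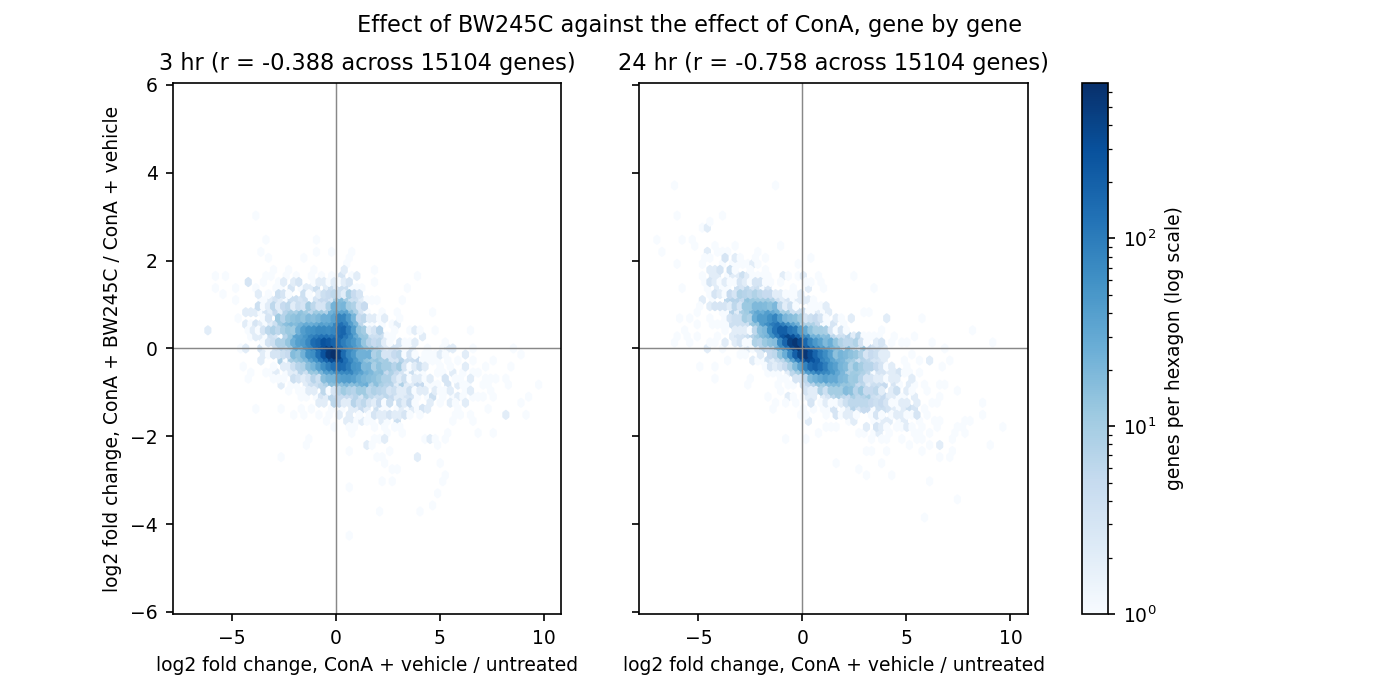
Log2 fold change of ConA + BW245C over ConA + vehicle (y axis) against that of ConA + vehicle over untreated (x axis) for 15104 genes at 3 hr (left) and 24 hr (right), with the shade giving genes per hexagon on a log scale. The cloud slopes downward at 24 hr, with r = -0.758, and less so at 3 hr, with r = -0.388.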

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

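The tests of slide and of other array splits were planned before their results were seen, while the tests of shared vehicle arrays, of hepatocyte share, of a smaller ConA response and of the clock genes were chosen after. In a group of 5, an array was singled out when its gap to the nearest other array was large against the group's range, which happens by chance in about 1 in 20 groups. By that measure 16 of 205 groups of list means and 74 of 1210 groups of single genes had such an array. Among scores and always-named genes these were ConA + vehicle 3 hr replicate 3 for the repressed score (gap 0.165) and replicate 1 for Tnf (0.835). The largest gaps in list means were exocrine pancreas markers in ConA + BW245C 24 hr replicate 4 (8.442), erythroid markers in ConA + BW245C 3 hr replicate 5 (-1.007) and cell cycle genes in ConA + vehicle 3 hr replicate 1 (0.671). The pancreatic genes Cela2a (8.814), Ctrb1 (7.888) and Amy2a5 (6.88) stood apart in that same ConA + BW245C 24 hr array, Csf3 in untreated replicate 5 (6.791) and Hao2 in ConA + vehicle 24 hr replicate 4 (2.997).

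The agonist's effect differed between 24 and 3 hr in 4535 genes. List means differed for P450 (1.011), hepatocyte secreted (0.568), bile acid (1.089), pericentral (1.046), urea cycle (0.547), cholesterol (0.751), acute phase (0.478), neutrophil (-1.135) and cytokine genes (-0.71). Single genes were Ihh (4.489), Cyp7a1 (3.946), Ddit4 (3.585), Cyp8b1 (3.311), Hao2 (3.206), Ppp1r3g (-4.388), Cxcl3 (-4.233), Sult1e1 (-4.065), Pdk4 (-3.848), Il13 (-3.383), Il4 (-2.061), Il10 (-1.7) and Ifng (-1.144). Features without a symbol numbered 9990 and were left out of the gene results, though 4835 changed with ConA at 3 hr, 5654 with ConA at 24 hr, 2688 with BW245C at 3 hr and 1285 with BW245C at 24 hr.

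Chance could be excluded for the gene counts, where only the real split, 1 of 100, called as many genes. The real counts and the highest of the other splits were 9363 and 5734 for ConA at 3 hr, 10399 and 6285 for ConA at 24 hr, 4317 and 2587 for BW245C at 3 hr, 4007 and 2464 for BW245C at 24 hr and 4535 and 2472 for the interaction. They were 10338 and 6515 for vehicle at 24 against 3 hr, and 10465 and 5549 at 3 hr and 8544 and 5402 at 24 hr for ConA + BW245C against untreated. The few splits within slides 3 (330 and 1, of 21) and 4 (369 and 3, of 35) also argue against chance. The number of lists called did not exclude chance, as 29 of 100 splits gave at least the 20 lists of ConA at 3 hr (highest 27), 29 the 28 of ConA at 24 hr (31), 71 the 9 of BW245C at 3 hr (24), 19 the 26 of BW245C at 24 hr (32) and 77 the 9 of the interaction (29).

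All BW245C arrays at 3 hr lay on slide 3, with 2 of the 5 vehicle arrays. Genes found across slides differed within slide 3 on arrays left over (median signed log2 difference 0.154, from 0.126 to 0.175). On average 73.6% of them kept their sign, always with the same 2 vehicle mice. This argues against slide as the whole cause. The difference within the slide was 0.298 (0.251 to 0.336) of that across slides, so slide, or another difference between vehicle mice 1 to 3 and 4 to 5, may be part of the cause. The size of the 3 hr effect is therefore uncertain.

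The BW245C change at 24 hr ran against the ConA change. It did so with the agonist effect taken within slide 4 (r = -0.674) and with split vehicle arrays (highest r -0.634), which argues against slide and shared arrays as the cause. Markers of resident cells rose (0.341, exact permutation p = 0.0238) while neutrophil markers fell (-1.188, p = 0.00794), which argues against a higher share of hepatocytes alone. Within slide 4 these were 0.311 (exact permutation p = 0.114) and -1.203 (p = 0.0286, the smallest possible), so the first did not pass within a slide. With no shared vehicle array, 93.3% (89.4 to 96.9) of the genes called with BW245C were called the opposite way with ConA, against 34.1% for independent calls. That is consistent with a smaller response to ConA, a hypothesis found and tested on the same data.

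The clock list was not called with BW245C at 3 hr (mean -0.459, adjusted p = 0.832), but its phase sets, split after that, differed by 2.04 (exact permutation p = 0.0159). Vehicle replicate 1 (1.329) lay within the BW245C range (1.105 to 2.191) and the other 4 below it (-1.297 to -0.182). It was 2.658 within slide 3 (exact permutation p = 0.0476), which argues against slide. Against untreated mice BW245C mice differed by 0.185 (exact permutation p = 0.437), which leaves open a smaller response to ConA. Of 18 clock genes 16 had the sign of 1 shift in phase, and time of day of collection cannot be told apart from treatment, since collection times were not given in the sources used here.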

How the results depend on the processing

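All alternatives were planned before the data were examined, except all features, the arrays of 1 slide, the overlap with split vehicle arrays and the permutation test of list means. The cause of a difference was not tested unless stated. The scan batch, in which slides are nested, was not run as a block of its own. With the slide as a block 1770 genes changed with BW245C at 3 hr, 923 in the interaction, and 5177 and 5513 in ConA + BW245C against untreated at 3 and 24 hr. With a random block the first 2 were 2647 and 2104. Using only the groups compared gave 2190 at 3 hr. A 2-fold minimum gave 3430, 4337, 572 and 641 genes for ConA and BW245C at 3 and 24 hr, 1170 for the interaction, 4415 for vehicle at 24 against 3 hr, and 3530 and 2687 for ConA + BW245C against untreated, fewer by construction, as with a threshold of 0.01 (2120 and 2283 for BW245C and 1887 for the interaction). All features gave 15922 genes for ConA at 24 hr, 6890 for BW245C at 3 hr, 7580 for the interaction, 17407 for ConA + BW245C at 3 hr and r = -0.271 at 3 hr. Arrays of 1 slide gave 330 and 369 genes for BW245C at 3 and 24 hr. With an estimated correlation 1, 0, 0, 0 and 0 lists were called for ConA at 3 and 24 hr, BW245C at 3 and 24 hr and the interaction.

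The 3 hr scores were sensitive. The slide block for them chose the score genes with the slide in the fit and compared only the mice of slide 3, while a slide term over all mice gave -0.328 and 0.21 for the main scores. The induced difference did not pass with the median of probes found on all arrays (-0.214), no filter (-0.188), the slide block (-0.31), the series matrix values (-0.143), no fold minimum (-0.044) or all features (-0.005). The repressed difference did not pass with normexp (0.096), quantile normalization (0.047), a filter on all 25 arrays (0.126), the slide block (0.15), no fold minimum (0.017) or a median over genes (0.138). Leaving out 1 mouse gave -0.283 to -0.166 for the induced score, which lost its call without 7 mice, and 0.103 to 0.184 for the repressed score, lost without 8. With the replicate number as a block the differences were -0.24 and 0.143 at 3 hr and -0.481 and 0.625 at 24 hr, where the smallest possible p of a sign-flip test was 0.0625.

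Normexp shrank 99 of 366 called single gene changes and 18 of 92 called list means by over 1.5 times, and raised none that far. Within a slide 82 of 149 named gene results lost calls, none turned and 2 of 141 called changes moved by over 1.5 times. On slide 3 BW245C calls at 3 hr had medians of 0.337 and -0.359, not 0.603 and -0.508. A sign turned in 5 results. Il10 at 24 against 3 hr with vehicle was -0.085 with normexp, the cytokine list of the interaction 0.126 with a filter on all 25 arrays, Il6 in the interaction 0.004 with the slide as a block, the hepatocyte secreted list with ConA at 3 hr -0.046 with quantile normalization, and Ctrb1 with BW245C at 24 hr -0.061 without ConA + BW245C replicate 4, none of which passed.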

Other observations

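Genes of prostaglandin synthesis and reception moved in both directions after ConA. At 3 hr 4 of 21 rose and 5 fell, with Ptgs2 at least 9.24-fold (adjusted p = 6.45e-09) and the receptor gene Ptger4 at least 3.04-fold (adjusted p = 2.86e-08) higher, and the constitutive cyclooxygenase Ptgs1 3.01-fold (adjusted p = 2.02e-08) and the thromboxane receptor gene Tbxa2r at least 7.54-fold (adjusted p = 2.22e-10) lower. At 24 hr 8 rose and 9 fell, with the prostacyclin synthase Ptgis 4.34-fold (adjusted p = 4.1e-09) higher and the prostaglandin-degrading enzyme Hpgd 3.14-fold (adjusted p = 3.35e-11) lower. The list as a whole was not called in either comparison (adjusted p = 0.937 and 0.812).

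A weaker ConA response with the agonist at 24 hr is consistent with the 93.3% of BW245C calls that ran opposite to ConA. It was not seen in every programme, as acute phase (mean 2.372 with ConA) and cell cycle genes (1.923) were not called with BW245C (-0.043 and 0.053, adjusted p = 0.827 and 0.714). Ptgdr was not well above background, so these arrays do not show which cells the agonist reached, and measuring Ptgdr in sorted liver cells, or giving BW245C to mice without Ptgdr, would test whether DP1 is needed. Slide may add to 3 hr gene changes (ratio 0.298), though score differences were larger within slide 3. Groups spread over slides would test it. Serum transaminases and histology were not analysed here, and would show whether fewer hepatocytes were injured. Collecting all groups at recorded times would separate the clock shift, with 16 of 18 genes in line with 1 phase, from time of day.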
